A study of Mus musculus with 2 samples.

How the data were processed

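The series holds DNase-seq of the left cerebral cortex of female B6CASTF1/J mice at postnatal day 4, an F1 hybrid of 2 inbred strains. DNase-seq maps bases that the enzyme DNase I cuts in chromatin; regions cut more than their surroundings are DNase I hypersensitive sites (DHSs). There is 1 group with 2 libraries, replicate 1 and replicate 2, which the labels give as separate animals by their animal numbers, with a single strain-level donor. No treatment, age or tissue was compared, so the comparisons are between the libraries, between gene lists, between genome parts and against shuffled or flanking sequence.

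Per the labels and the file headers, the deposited files are in mm10 coordinates and were made separately for each library, with no pooling. The aligner, the caller, the versions and the settings are not given in the sources used here. The 2 peak lists of a library hold the authors' signal value for each call, a tag density whose scaling the headers do not state. In each library the signal values under 100 steps were whole multiples of a single step (100% of those tested, within 0.05 of a step), as a density per 1000000 tags would give. A step of 0.00467 in replicate 1 and of 0.00788 in replicate 2 would stand for 1 tag if the library held 214 and 127 times 1000000 tags. These depths are implied, not stated, so signal values of the libraries are given side by side. Apart from their correlation, values were compared between libraries only to scale a limit, to test for extra DNA copies and to match DHSs by implied tags. The file of the cut rate holds the authors' false discovery rates (q-values) per run of bases, listed only under 0.05. The deposited footprint files list short protected intervals inside cut regions and carry the value 0.01 on every line, taken here as a threshold p-value or false discovery rate and not as a measurement. Every call of the stricter list held a base with a false discovery rate under 0.001, and all but 1 call of the lenient lists a base under 0.05. The stricter list was used throughout, and the lenient list was an alternative. Genes said to have no promoter call lack one in the stricter list, and some of them had one in the lenient list.

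The reference was the mm10 genome (GRCm38) with the GENCODE M21 basic annotation. A shared DHS was the union of overlapping calls (1 bp or more) that held a call of each library. A promoter DHS lay within 1 kb of the transcription start site (TSS) of a basic transcript of a protein-coding gene; other DHSs were assigned to exons, introns or intergenic sequence in that order, and all of these are called distal. Overlap shares carry exact 95% binomial intervals, which cover counting error only, and were set beside 100 shuffles of the intervals within their chromosomes outside assembly gaps. For 23 gene lists, the share of genes with a shared promoter DHS was compared with all other protein-coding genes by Fisher's exact test. The number of distal shared DHSs whose nearest TSS belonged to the list was compared with 10000 random lists matched on gene territory in 10 groups, by a permutation test whose smallest p is 0.0002. Matches to 28 consensus sequences were counted in the central 150 bp of shared DHSs and in windows 1 kb to either side outside calls, by Fisher's exact test; ratios divide the shares, with fewer than 3 background matches set to 3. Footprints were compared by overlap, beside 20 shuffles inside the DHSs. The shared DHSs per Mb of chromosome X were ranked among the 20 chromosomes other than Y. All tests were two-sided, with Benjamini-Hochberg adjustment within each family at 0.05. Genes and DHSs are not biological replicates, so each library's own value was computed too.

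The gene lists, the consensus sequences, the tests and all but 2 kinds of the alternatives were fixed before the data were examined. Named genes were, in each list, the 2 with the highest mean rank of promoter signal value, the 2 with the most distal shared DHSs and the first 2 in alphabetical order without a promoter call in either library (all of them where there were 5 or fewer), with 10 fixed genes and the 10 genes with the most distal shared DHSs; of the consensus sequences, the 5 highest and the 3 lowest ratios. The text gives a selection of these, and some of the named genes are not reported here. The alternatives were other overlap rules, stronger or equally long lists, the lenient list, promoter windows of 0.5 and 2.5 kb, genes with CpG-poor promoters alone (observed to expected CpG ratio under 0.6 within 500 bp of the TSS), distal DHSs within 100 kb alone, GC-matched windows in bins of 2%, base-shuffled consensus sequences, whole intervals, DHSs per gene, and each library alone. GC-matched windows were drawn more than once where a bin held too few flanking windows. Each shuffled count was the mean over 20 shuffled versions of a consensus in the same DHS windows. Fisher's exact test took both as independent windows, so these p-values are approximate. Leaving out calls with signal values under 0.3, and leaving out windows with a CTCF match, were chosen after seeing the data and the simulations. The limit scaled by the ratio of the libraries, used only to count calls and stretches under it in replicate 2, was also chosen after seeing the data.

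The steps were tested on simulated data. Lists of 20 genes raised to 97% or lowered to 5% with a promoter DHS were recovered in 100% and 100% of draws, and 2.8% of unchanged lists were called. Lists with 4-fold distal counts were recovered in 88% of draws with a median ratio of 3.74, and 0% of unchanged lists were called. All 5 planted consensus sequences were recovered, and 1 that was not planted was called, the NEUROD E-box, whose matches can lie inside CTCF matches. The simulated promoter DHSs were placed without regard to CpG content, and the distal counts in proportion to gene territory. The simulated sequences had equal base shares in DHS windows and background. False calls under CpG differences, clustered counts or differing GC were therefore not tested. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, bedtools 2.31.1 and matplotlib 3.10.9 were used. The reads, and the 2 alleles of the hybrid, were not analysed here.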

Results

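DNase-seq libraries of the left cerebral cortex of 2 female B6CASTF1/J mice at postnatal day 4 gave 59355 DHS calls in replicate 1 and 46566 in replicate 2. Median call widths were 200 and 208 bp. The authors' signal value had a median of 0.556 in replicate 1, with quartiles of 0.163 and 1.09, and of 1.45 in replicate 2, with quartiles of 0.874 and 2.83. In replicate 1, 25251 calls (42.5%) had a signal value under 0.3, against 1113 (2.39%) in replicate 2. The same limit is not the same level in both libraries: at DHSs called in both, the median ratio of the values, replicate 2 to replicate 1, was 2.13. With the limit for replicate 2 scaled by this ratio to 0.638, a choice made after seeing the data, 5785 of its calls (12.4%) lay under it. The scaling of the values is not stated, so a higher value in 1 library is not read as more open chromatin. Footprint calls numbered 153911 in replicate 1 and 224652 in replicate 2, with median widths of 8 and 9 bp.

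**Figure D1:**
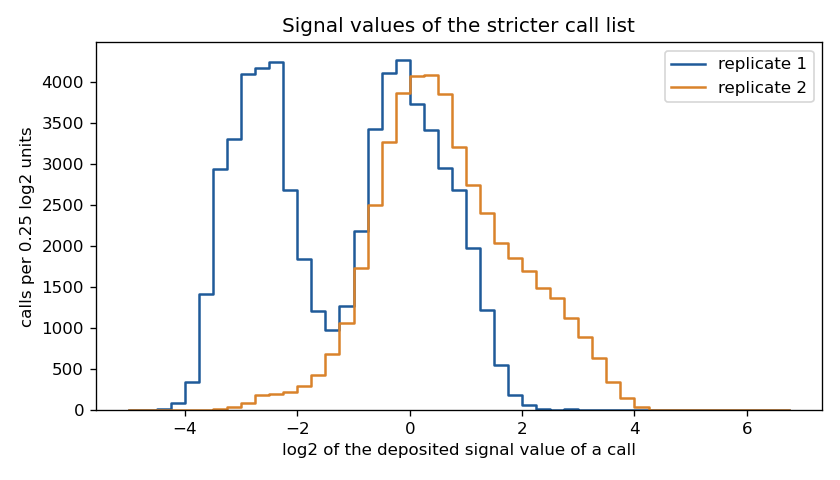
Calls of the stricter list per bin of 0.25 on the log2 scale of the authors' signal value (x axis), as the number of calls (y axis), with 1 line per library. Replicate 1 has a separate low mode, with 42.5% of its calls under 0.3; replicate 2 has 2.39% there, and 12.4% under the scaled limit of 0.638.

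The first question was which DHSs both animals held. Of the replicate 1 calls, 28535 (48.1%, 95% interval 47.7 to 48.5) overlapped a call of replicate 2, against 0.919% after shuffling. Of the replicate 2 calls, 28286 (60.7%, 60.3 to 61.2) overlapped a call of replicate 1, against 1.17% after shuffling. They formed 26012 shared DHSs, with a median width of 300 bp and 9.55 Mb in all. Across shared DHSs, which are not independent replicates, the log2 signal values of the libraries had a Pearson r of 0.91 (Spearman rho 0.907). Replicate 1 calls that were absent even from the lenient list of replicate 2 numbered 28893, with a median signal value of 0.163. With calls under 0.3 left out, an alternative chosen after seeing the data, 82.7% of the replicate 1 calls were overlapped; among the stronger 50% of each list the share was 71.0%, and among the strongest 20000 it was 85.6%. The lenient lists gave 42999 shared DHSs.

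Shared DHSs were concentrated at the starts of genes. Promoters held 14285 (54.9%, 54.3 to 55.5), 24.8 times the shuffled share of 2.22%. Introns held 4916 (18.9% against 43.2% shuffled), intergenic sequence 5421 (20.8% against 50.9%) and other exons 1390 (5.34% against 3.72%). The promoter share was 31.0% among all calls of replicate 1 and 41.4% among those of replicate 2. A shared promoter DHS was present at 12202 of 21911 protein-coding genes (55.7%). It was present at 90.4% of genes with CpG-richer promoters and at 20.2% of genes with CpG-poor promoters.

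The second question was which gene groups carried promoter DHSs in the neonatal cortex. Regulators and markers of upper cortical layers carried one at 12 of 12 genes (exact adjusted p = 0.00346, Fisher's exact test), activity-regulated genes at 15 of 15 (exact adjusted p = 0.000712), synaptic genes at 17 of 18 (exact adjusted p = 0.00109) and housekeeping genes at 18 of 18 (exact adjusted p = 0.000168). Among upper-layer genes, Pou3f3, a POU-domain transcription factor, had promoter signal values of 1.44 in replicate 1 and 8.48 in replicate 2, and Lhx2, a LIM homeodomain factor, 1.32 and 5.31. Fosb, an AP-1 subunit induced by neuronal activity, had 2.26 and 8.27, and Fos had 2.11 and 3.88. The synaptic scaffold gene Homer1 had 2.17 and 7.96, and Vamp2, a synaptic vesicle SNARE, 1.84 and 5.92. The housekeeping genes Rplp0 and Ppia had the highest values of their list, 4.49 and 15.5 for Rplp0 and 3.58 and 13.1 for Ppia. Among genes with CpG-poor promoters, of these lists only synaptic genes passed, at 87.5% against 20.1% of other genes (exact adjusted p = 0.000981, Fisher's exact test). There housekeeping genes had 3 of 3 (exact adjusted p = 0.0602) and activity-regulated genes 1 of 1 (0.296), and no upper-layer gene had such a promoter.

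Other neural lists, and the imprinted genes, did not pass this test. Glutamatergic markers had a shared promoter DHS at 9 of 16 genes (exact adjusted p = 1), deep-layer genes at 9 of 13 (0.448), cortical interneuron genes at 12 of 21 (1), radial glia and progenitor genes at 11 of 16 (0.395), astrocyte genes at 8 of 18 (0.406), oligodendrocyte precursor genes at 5 of 13 (0.341) and imprinted genes at 16 of 21 (0.105), all Fisher's exact tests. In replicate 2 alone, 14 of 16 glutamatergic genes had a promoter DHS (exact adjusted p = 0.0573), so that 5 genes, the proneural Neurod2 among them, had a call in that library only. Oligodendrocyte precursor genes reached 9 of 13 in replicate 2 alone (exact adjusted p = 0.609), above the share of other genes, where the main value lay below it. Imprinted genes passed in replicate 1 alone, at 17 of 21 (exact adjusted p = 0.0456), and within 2.5 kb of the TSS (85.7%, 0.0125). Of deep-layer genes, Tle4, a Groucho-type corepressor, had values of 3.06 and 19.5, while Sox5 and Nxph4 had no promoter call in either library. Interneuron genes without one included Dlx1 and Lhx6, and Gad1, which makes the GABA-synthesising enzyme, had 0.883 and 1.76. Progenitor genes included Top2a, a topoisomerase of dividing cells, at 3.25 and 5.51, whereas Eomes and Nes had no call in the stricter list. In the lenient lists Nes had a promoter call in each library and Eomes in replicate 2 only. The astrocyte gene Clu had 1.99 and 6.51, and Pdgfra, the receptor that marks oligodendrocyte precursors, 1.24 and 2.97.

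Lists of other cell types and regions carried fewer promoter DHSs. None of 39 Hox genes had a shared one (0%, 95% interval 0 to 9.03, exact adjusted p = 1.8e-13), and none of 16 hepatocyte genes (exact adjusted p = 1.68e-05) or 15 lymphocyte genes did (exact adjusted p = 2.85e-05, all Fisher's exact tests). The share was 1 of 16 muscle genes (exact adjusted p = 0.000178), 1 of 13 erythroid genes (0.00101), 1 of 15 germline genes (0.000324) and 1 of 1134 olfactory receptor genes, whose Fisher's exact p underflowed to 0. Single libraries called 4 Hox promoters in replicate 1 and 3 others in replicate 2, and within 2.5 kb of the TSS 5.13% had a shared DHS. In that window hepatocyte genes had 12.5%, muscle genes 12.5%, lymphocyte genes 6.67%, germline genes 13.3% and erythroid genes 15.4%, all still passing as lower. In replicate 2 alone 23.1% of erythroid, 23.5% of microglial and 12.5% of muscle genes had a promoter DHS (exact adjusted p = 0.017, 0.00538 and 0.000375), and in replicate 1 alone 5.88% of microglial genes did. Single libraries gave 0.529% and 0.441% of olfactory receptor genes, 28.6% of meningeal genes in each, and 28.6% and 35.7% of myelinating genes. Microglial genes had 2 of 17 (exact adjusted p = 0.000712), with no call at C1qa or Aif1. Meningeal and choroid plexus genes had 2 of 14 (exact adjusted p = 0.00371), namely Col1a1 and the ciliogenesis regulator Foxj1. Regulators of subcortical regions and hindbrain had 6 of 20 (exact adjusted p = 0.0348), with none at En1 or Barhl1. Endothelial and mural genes had 6 of 20 (exact adjusted p = 0.0348), with Slc2a1, the glucose transporter of the blood-brain barrier, at 1.64 and 3.38 and none at Cldn5. Myelinating oligodendrocyte genes had 3 of 14 (exact adjusted p = 0.0218), with none at Cldn11 or Aspa. The lenient lists held a promoter call at Cldn11 in each library. Leaving out a library ended the calls of 4 lists: in replicate 1 alone the exact adjusted p was 0.0784 for myelinating, 0.235 for endothelial and 0.0784 for meningeal genes, and in replicate 2 alone it was 0.112 for myelinating, 0.0921 for endothelial and 0.0921 for subcortical genes. In the lenient lists these 4 had 42.9% to 50% of genes with a shared promoter DHS (exact adjusted p from 0.25 to 0.479), and within 2.5 kb of the TSS myelinating genes had 28.6% (0.078) and endothelial genes 35% (0.0914). Among CpG-poor promoters, olfactory receptors were the 1 list still called lower, at 0.0883% against 22.5% of other genes (exact adjusted p = 1.27e-114). There the Hox (0 of 12), hepatocyte (0 of 16), muscle (0 of 15), lymphocyte (0 of 14), endothelial (0 of 12), myelinating (0 of 10) and germline genes (0 of 10) were at 0% against 20.2% of other genes, with exact adjusted p from 0.201 to 0.296. Microglial genes were at 6.67% (exact adjusted p = 0.405), erythroid genes at 7.69% (0.564) and meningeal genes at 11.1% (0.767), while 2 of 2 subcortical genes had a DHS (0.201). The subcortical genes without a shared DHS thus all had CpG-richer promoters. The Hox genes outside the 12 had CpG-richer promoters and none had a shared DHS there, against 90.4% of all genes with such promoters.

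**Figure D2:**
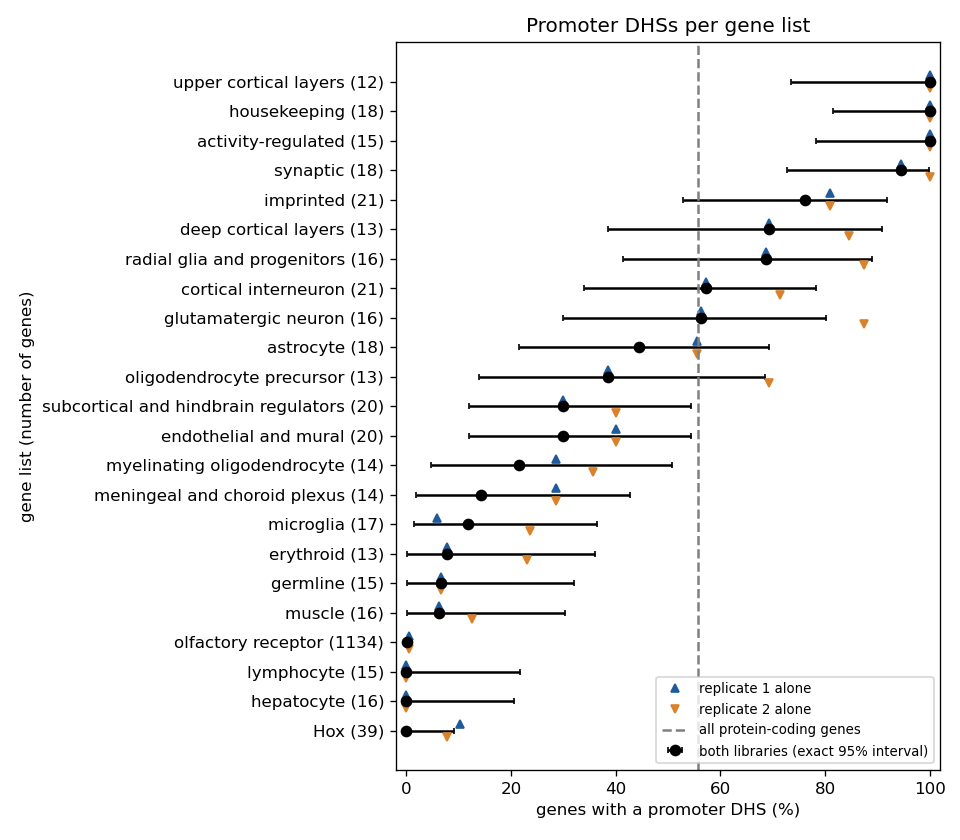
Share of genes with a promoter DHS (x axis, percent) for each of 23 gene lists (y axis, with the number of genes); circles are shared DHSs with exact 95% intervals, triangles each library alone, and the dashed line the 55.7% of all protein-coding genes. A shared DHS is a union of calls, so it can reach a promoter window that the call of 1 library does not, as at microglial genes, where both libraries give 11.8% and replicate 1 alone 5.88%.

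Genes fixed beforehand also differed at single loci. The promoter of Fos was covered at chromosome 12, 85473541 to 85474100, and flanked by an intergenic DHS at 85485981 to 85486280 with values of 2.55 and 6.66. Neurod2 and Olig2 had a promoter call in replicate 2 only, with values of 4.02 and 2.10. Gfap, Cx3cr1 and Alb had none in the stricter list. A shared DHS at chromosome 11, 102900881 to 102901100, overlapped the upstream end of the Gfap gene, outside the promoter windows of its basic transcripts, with values of 1.32 and 2.75. The distal DHS near a fixed gene with the highest geometric mean of both signal values, picked after the values were seen, lay upstream of Neurod2 in intergenic sequence at chromosome 11, 98342661 to 98342900, with values of 3.88 and 8.86. In replicate 2 an exonic DHS near Cx3cr1 had a higher value, 8.96. The site upstream of Neurod2 is called the Neurod2 DHS only because it lay within 50 kb of that gene. A promoter DHS of another gene, at 98348501 to 98348747, was closer to it than the start of Neurod2. By nearest TSS it is therefore not counted for Neurod2, and no link to that gene was tested. The 240 bp of the Neurod2 DHS had a GC content of 59.2% and held a match to 1 of the 28 consensus sequences, that of CTCF (CCASYAGRKGGC). The reference sequence of the Neurod2 DHS is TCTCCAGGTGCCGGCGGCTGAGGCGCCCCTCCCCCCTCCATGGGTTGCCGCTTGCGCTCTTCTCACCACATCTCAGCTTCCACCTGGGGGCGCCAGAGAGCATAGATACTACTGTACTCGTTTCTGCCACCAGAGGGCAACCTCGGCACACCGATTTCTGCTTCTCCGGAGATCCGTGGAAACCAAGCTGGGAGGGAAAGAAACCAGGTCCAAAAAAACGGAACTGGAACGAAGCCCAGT.

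Distal DHSs were more numerous than in matched random lists near 3 groups. Activity-regulated genes had 34 against 8.30 (ratio 4.10, permutation adjusted p = 0.0046, permutation test), with 7 nearest Ier2 and 4 nearest Dusp1. Endothelial and mural genes had 42 against 14.9 (2.82, permutation adjusted p = 0.0153), of which 24 were nearest Cdh5, the gene of vascular cadherin. Glutamatergic genes had 36 against 14.7 (2.45, permutation adjusted p = 0.0494), with 13 nearest Mef2c and 5 nearest Neurod1. Olfactory receptor genes had fewer, 56 against 287 (0.195, permutation adjusted p = 0.0046). In replicate 1 alone none of the 3 passed, with ratios of 2.00 for activity-regulated (permutation adjusted p = 0.677), 1.95 for endothelial (0.677) and 1.09 for glutamatergic genes (0.888); in replicate 2 alone they were 3.76 (0.0092), 2.25 (0.0506) and 1.89 (0.0966). The endothelial ratio was 0.872 among the stronger 50% of the calls and 1.65 with calls under 0.3 left out (permutation adjusted p = 0.277), and within 100 kb the glutamatergic ratio was 2.13 (0.143).

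The remaining 19 lists did not pass. Ratios above 1.5 were seen for housekeeping (3.13, permutation adjusted p = 0.0561), lymphocyte (2.33, 0.167), radial glia and progenitor (2.25, 0.0767), upper-layer (1.99, 0.163), microglia (1.93, 0.225), astrocyte (1.87, 0.163), oligodendrocyte precursor (1.79, 0.302), myelinating oligodendrocyte (1.73, 0.346) and imprinted genes (1.69, 0.2), all permutation tests. Imprinted genes passed in replicate 2 alone (2.38, permutation adjusted p = 0.0184), and housekeeping genes among the stronger 50% of the calls (3.50, 0.0299) and with calls under 0.3 left out (3.21, 0.0333). In replicate 1 alone the ratios were 1.37 for housekeeping and 1.31 for imprinted genes (permutation adjusted p = 0.758 for both), and in replicate 2 alone housekeeping genes had 2.41 (0.127). Replicate 1 alone also gave 1.05 for microglia, 1.52 for lymphocyte, 0.944 for astrocyte and 0.0867 for erythroid genes, and replicate 2 alone 1.69, 1.78, 2.03 and 0.229, none past the threshold. The other lists were deep layers (1.35), interneurons (1.29), hepatocyte (1.19), Hox (1.08), muscle (1.02), synaptic (1.01), meningeal and choroid plexus (0.997), subcortical and hindbrain (0.906), germline (0.431) and erythroid (0.243). Of these, in replicate 1 alone, hepatocyte genes had 2.53, Hox 2.55, muscle 0.666 and synaptic genes 0.509, and in replicate 2 alone subcortical genes had 1.68, again none past the threshold. Single genes with the most distal DHSs were Cdh5 with 24, then B4galt5, Mid1, Olfr1324, Pou3f3, Sfi1, Trappc9 and Vstm2l with 15 each, and Gm21860 and Sorl1 with 14. These counts per gene were not matched on gene territory, which ranged from 90.6 kb for B4galt5 to 3198 kb for Sfi1. Gm21860 lies on chromosome Y, although both animals are labelled female. Regulation of these genes by the DHSs was not tested.

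Promoter and distal DHSs held different sequences. CTCF, the factor of chromatin loop anchors, had the highest distal ratio: 2070 of 11727 distal windows (17.7%) held its consensus, against 0.0898% of flanking windows, a ratio of 196 whose Fisher's exact p underflowed to 0, and against 0.931% of promoter windows. The ratio was 114 in replicate 1 alone. The next were EGR (12.3, exact adjusted p = 7.51e-31), CRE (11.6, 2.16e-19), RFX (11.5, 6.91e-21) and YY1 (6.59, 1.24e-06), all Fisher's exact tests. In promoters the highest were NRF1, a regulator of nuclear genes for mitochondria (63.6, exact adjusted p = 3.46e-89), YY1 (47.9, 8.5e-98), CRE, the element bound by CREB (27.9, 6.71e-88), EGR (24.7, 3.43e-198) and ETS (24.2, 8.17e-50). Median GC was 67.3% in promoter windows and 44.7% in their flanks, and 55.3% and 46.7% for distal windows. Against GC-matched windows the promoter ratios were 23.8 for NRF1, 11.2 for YY1, 87.0 for CRE, 1.26 for EGR and 37.7 for ETS, and the distal ratios were 1.61 for EGR, 6.18 for CRE and 3.86 for YY1. With 261 CRE and 151 ETS matches in promoter DHSs, the ratios of 87.0 and 37.7 rest on few matches in the GC-matched windows. Their rise over the ratios to flanks is therefore not read as a stronger enrichment. In replicate 1 alone the distal ratios fell to 5.22 for EGR, 2.82 for CRE, 3.71 for RFX and 2.09 for YY1. The promoter ratio of YY1 was above that of NRF1 in replicate 1 alone (69.5 and 52.0) and below it in replicate 2 alone (42.0 and 74.3). Against base-shuffled versions of each consensus the distal ratios of EGR (1.23, exact adjusted p = 0.269) and YY1 (1.93, 0.104) no longer passed, while those of CTCF and CRE were 414 and 2, and promoter ratios were 23.8 for NRF1, 14.9 for YY1, 9.67 for CRE, 1.28 for EGR and 11.6 for ETS.

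The NEUROD E-box, bound by neuronal basic helix-loop-helix factors, was more frequent in distal DHSs than in flanks (1.62, exact adjusted p = 1.88e-13, Fisher's exact test) and less frequent in promoters (0.482, exact adjusted p = 4.38e-15). It was named after the simulations, and its distal ratio was 1.35 without windows that held a CTCF match (exact adjusted p = 7.47e-05). Against its shuffled versions the promoter ratio turned to 1.09 (exact adjusted p = 0.596). HNF1 had 0 matches in distal DHSs and 0 in their flanks, so it has no ratio. The lowest distal ratios were those of the TATA box (0.242, exact adjusted p = 1.38e-11) and the OLIG E-box (0.35, exact adjusted p = 2.56e-15). Against GC-matched windows the TATA box no longer passed (0.667, exact adjusted p = 0.333), while the OLIG E-box had 0.333; in replicate 1 alone the TATA box had 0.394 and the OLIG E-box 0.675. Against shuffled versions they had 0.714 (exact adjusted p = 0.46) and 0.644 (0.0223). In promoters NFI, NR2F and HNF1 had 0 matches, but their flanks held only 2, 1 and 0 of 22897, too few to show a difference. The lowest promoter ratios past the threshold, named after the values were seen, were those of the LHX homeobox (0.0419, exact adjusted p = 9.87e-53; 1.14 and 1 against GC-matched windows, 0.421 and 0.0811 against shuffled versions, and ratios of 0.0687 and 0.0891 in replicates 1 and 2 alone) and the OLIG E-box (0.114, exact adjusted p = 2.17e-31; 0.315 and 1.85e-05). In promoters 12 of the 28 consensus sequences were higher and 12 lower; against GC-matched windows 14 were higher and 5 lower, and against their own shuffled versions 15 and 2. POU, MEF2 and the TATA box, named after the values were seen, turned from lower to higher calls: from 0.487 to 6.55 for POU (exact adjusted p = 4.89e-07 and 1.17e-09), from 0.408 to 5 for MEF2 (0.0013 and 0.00345) and from 0.302 to 5 for the TATA box (4.62e-13 and 3.21e-05) against GC-matched windows, and to 6.56, 5 and 3.18 against shuffled versions. In distal DHSs 12 were higher and 6 lower, with 12 and 12 higher and 3 and 2 lower under those settings. Under those settings the p-values are approximate, and reuse of GC-matched windows can make them too small. AP-1, named after the values were seen, was 1 of the 6 lower (0.844, exact adjusted p = 0.0487), but in replicate 1 alone it passed in the opposite direction (1.101, 0.0334), and in replicate 2 alone it had 1.06 (0.351). It did not pass against GC-matched windows (1.017), against shuffled versions (1.004) or without windows that held a CTCF match (0.864). MEF2, also named afterwards, did not pass (1.32, exact adjusted p = 0.368), and passed as lower in replicate 1 alone (0.473, 2.57e-05) and as higher in replicate 2 alone (1.503, 0.0178). It passed as higher against GC-matched windows (6, exact adjusted p = 0.000625) and shuffled versions (3, 0.0162), all Fisher's exact tests.

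**Figure D3:**
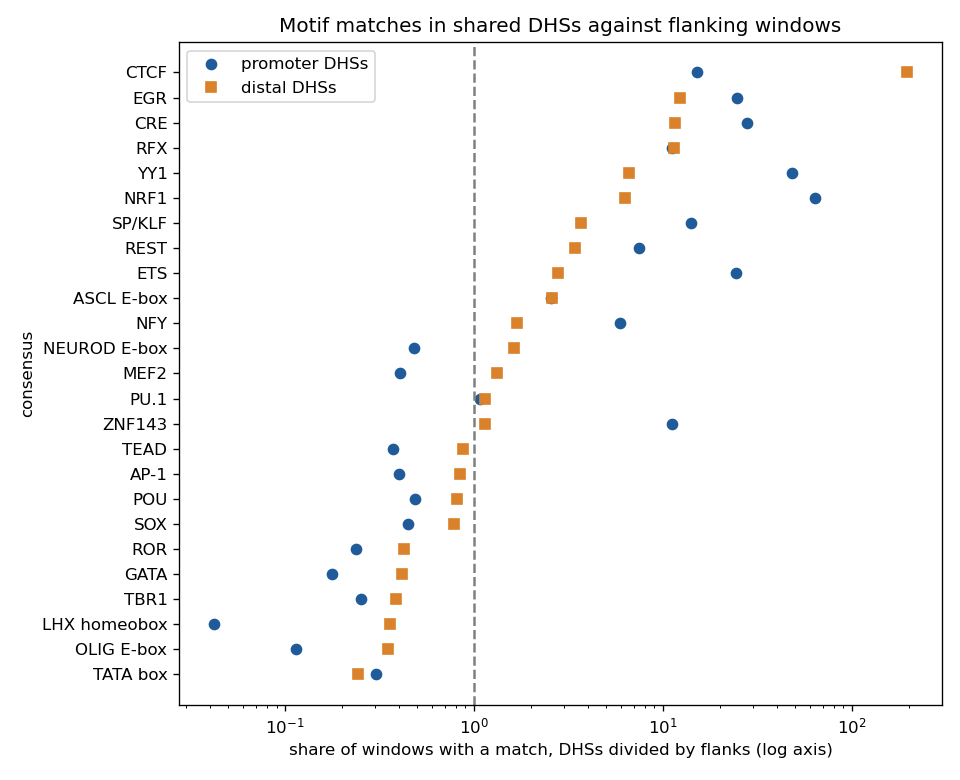
Share of windows with a consensus match in shared DHSs divided by the share in flanking windows (x axis, log scale), for each consensus (y axis) in promoter DHSs (circles) and distal DHSs (squares); NFI, NR2F and HNF1, with no match in promoters, are not drawn. CTCF has the highest distal ratio, 196, and NRF1 the highest promoter ratio, 63.6.

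Footprints marked most shared DHSs in both animals. Of shared DHSs, 23689 (91.1%, 90.7 to 91.4) held a footprint call of each library, distal ones more often (93.0%) than promoter ones (89.5%, p = 7.88e-23, Fisher's exact test). Single footprints were less often common: 42.6% of those of replicate 1 (42.4 to 42.9) and 27.4% of those of replicate 2 (27.2 to 27.6) overlapped one of the other library. Inside shared DHSs the shares were 61.4% and 39.9%, against 32.3% and 22.8% after shuffling within the DHSs. At least 50% overlap of both footprints left 25.5% and 17.5%.

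Chromosome X carried the fewest shared DHSs of the 20 chromosomes ranked, which are the 19 autosomes and X. It had 4.31 per Mb, against an autosomal median of 10.7 and a range of 7.88 to 17.2, a ratio of 0.405. Both animals are female, with 1 X inactivated in each cell. The exact p was 0.1, the smallest that a two-sided rank among 20 chromosomes allows, so this design cannot pass 0.05.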

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

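The tests of a calling threshold, of the library's tag number and of the number of genes on chromosome X were chosen after the result was seen; the other tests were set before theirs.

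Chromosome Y, which had no comparison of its own, held 39 calls in replicate 1 and 35 in replicate 2, although both animals are labelled female. Its 24 shared DHSs are counted among the 26012. The central 50 bases of 20 and 15 of these calls occurred elsewhere in the genome, 13 and 9 of them on another chromosome, and 14 of the 24 shared DHSs on Y had as their nearest gene Gm21860.

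Replicate 1 held 861 stretches of at least 10 calls under 0.3 with gaps of at most 5 kb, with 16289 calls and a median length of 12.9 kb, and replicate 2 held 23, or 53 with the limit scaled to 0.638, chosen after the result was seen. Broad open domains of both animals also stay undecided. Of stretch bases, 59.3% were under the authors' FDR limit in replicate 1 and 2.48% in replicate 2, a ratio of 0.0419. The ratio was below the limit set for this test, but the stretches were picked by calls of replicate 1. It also cannot tell domains absent from replicate 2 from domains too weak to be called there. A calling threshold that passed lower densities inside the stretches stays open: outside them 87.3% of calls found only in the lenient list were denser than the median stretch call, but this decides nothing, since the stretches were picked by low values. Extra copies of this DNA in replicate 1 stay open, since the log2 difference of the signal values, replicate 1 minus replicate 2, had a median that was higher by 0.38 in the 440 shared DHSs inside than in those outside (95% bootstrap interval 0.29 to 0.44), which spans the 0.3 set for this test. These stretches were picked by calls of replicate 1. The difference therefore cannot tell extra copies from another local rise of that library's signal. No other explanation was tested.

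Replicate 2 had more footprints than replicate 1, with a ratio of replicate 1 to 2 of 0.685. If the implied depths hold, the tag number of the library argues the other way. The steps imply 214 times 1000000 tags in replicate 1 and 127 times 1000000 in replicate 2. Implied tags of a DHS were taken from its highest signal value in each library. Inside shared DHSs they went the same way as the footprints. Their median was 243 in replicate 1 and 302 in replicate 2, and 73.2% of shared DHSs had more in replicate 2. In 4772 shared DHSs whose implied tags differed by under 10% the ratio was 0.73 (0.716 to 0.743). As far as these numbers stand for the tags inside each DHS, such tags do not account for it as a whole. What differs between the libraries, such as digestion or fragment choice, stays open, and no biological explanation was tested.

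Chromosome X had fewer shared DHSs also per gene, at 0.828 of the lowest autosome, which argues against the number of genes as the whole cause. CpG-poor promoters were more common on X (69.5% of genes against 48.1%), but among CpG-richer promoters 84.4% held a shared DHS on X against 90.6% on autosomes, a difference of -6.15 percentage points with intervals that do not overlap. Among CpG-poor promoters X and autosomes had 19.7% (16.8 to 23.0) and 20.6% (19.8 to 21.4), so the makeup of promoters is argued against only as the whole cause. It may carry most of the gap in promoter DHSs, since these shares differed far more between the classes than between X and autosomes within a class. Distal DHSs are not covered by these shares. Lower signal per DHS may contribute, since the median value at CpG-richer promoters on X was 0.553 of that on autosomes in replicate 1 and 0.534 in replicate 2. The inactive X is an open explanation that was not tested, since both animals are female.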

How the results depend on the processing

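The alternatives without calls under 0.3 and without CTCF windows were chosen after the result was seen. Chromosome X stayed lowest under all 5 of its alternatives. The share of replicate 1 calls overlapped was 34.4% with 50% of both intervals overlapping, 46.5% with 50% of the shorter, 71.0% in the stronger 50%, 85.6% in the strongest 20000, 51.2% in the lenient list and 82.7% without calls under 0.3; for replicate 2 it was 43.8%, 58.9%, 88.8%, 85.3%, 58.1% and 61.6%. The lenient list gave 42999 shared DHSs and a promoter share of 40.3%, and single libraries a promoter share of 31.0% to 41.4%. Footprint overlap was 25.5% and 17.5% with 50% of both overlapping and 61.4% and 39.9% inside shared DHSs; DHSs with a footprint were 95.9% in the stronger 50% and 93.0% to 95.01% with the footprints of a single library. Values for other or single lists follow from the lists used, and those for 50% overlap from the stricter overlap rule on the lists as they were.

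CpG-poor promoters left 1 list higher and 1 lower, with far fewer genes per list, and 12 other calls no longer passed with the direction kept, while the subcortical list turned; no upper-layer gene had one, so that list has no value there. Lists whose side of the other genes turned, none of them past the threshold there, were, for promoters, glutamatergic (50% at 500 bp, 43.8% in the stronger 50%, 56.2% to 87.5% in single libraries), interneuron (52.4%, 57.1% at 2.5 kb, 33.3%), subcortical (100% of CpG-poor genes) and oligodendrocyte precursor genes (61.5% in the lenient list, 38.5% to 69.2% in single libraries). For distal DHSs the ratios in the stronger 50% were 0.682 for deep layers, 0.955 for interneurons, 0.872 for endothelial, 1.03 for meningeal and 0.919 for Hox genes. Single libraries gave 0 (replicate 1) to 2 higher lists, and ratios of 0.944 to 2.03 for astrocyte, 0.509 to 1.27 for synaptic, 0.666 to 1.34 for muscle, 0.778 to 1.101 for meningeal, 0.75 to 2.55 for Hox, 0.851 to 1.68 for subcortical and 0.964 to 2.53 for hepatocyte genes; calls under 0.3 left out gave 1.01 for meningeal genes. The cause was not tested.

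Lower consensus sequences numbered 5 in promoters and 3 in distal DHSs against GC-matched windows, and 2 and 2 against shuffled versions. NR2F turned to 1.27 with whole promoter intervals and NFI from 0 to 1.56 between single libraries, neither past the threshold; of all 28, GC matching turned 7 in promoters and 6 in distal DHSs, and shuffling 8 and 6, and promoter POU, MEF2 and the TATA box passed the threshold in the opposite direction under both (6.55, 5 and 5 against GC-matched windows). In distal DHSs replicate 1 alone turned 4 and replicate 2 alone 3. In replicate 1 alone AP-1 (1.101, from 0.844) and MEF2 (0.473, from 1.32) passed in the opposite direction. Distal POU, at 0.816 without passing, passed as higher against GC-matched windows (1.73) and shuffled versions (3.4). MEF2 also passed as higher against both (6 and 3), and SOX and TEAD did so against shuffled versions (1.69 and 1.64). The cause was not tested. Depth is only implied by the steps of the signal values, so how far it limits these results is not known.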

Other observations

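The test of footprints over consensus matches was set before its result was seen; the NEUROD E-box outside CTCF matches was added after. In shared DHSs, CTCF matches were covered by a footprint at 94.2% in replicate 1 and 97.6% in replicate 2, against 5.67% and 14.9% of matches to shuffled versions. NRF1 matches reached 53.6% and 84.5%, CRE matches 43.9% and 74.9% and RFX matches 36.2% and 63.5%. NEUROD E-box matches outside CTCF matches reached 14.7% (12.5 to 17.0) and 24.7% (22.0 to 27.4), against 11.1% and 16.3% of shuffled versions anywhere in shared DHSs, and 22.5% and 31.8% with the matches inside CTCF matches counted. The hypothesis that footprints lie on most of the consensus sequences was not borne out: 10 of 28 were covered more often than their shuffled versions in both libraries, by Fisher's exact test with adjustment. HNF1, with 0 matches, and REST and NR2F, with 1 shuffled match each, could not pass. AP-1 was covered less often in both; the consensus sequences named here were picked after the values were seen.

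The shared DHS with the highest signal values, 50.7 and 77.9, lay in an intron at chromosome 17, 39846781 to 39846900, with 2 copies of its central 50 bases in the genome. The centres of those at chromosome 16, 11144171 to 11144320, and chromosome 3, 5860361 to 5860530, had 4 and 6 copies. Of the 10 strongest, 5 had 1 copy, among them those on chromosomes 15 and 9 with values of 47.1 and 32.4 and of 28.4 and 34.0. Only exact copies in the reference chromosomes were counted. Copies that differ in sequence or are missing from the reference are therefore not excluded at any of these sites.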
